A study of Homo sapiens with 22 samples.

How the data were processed

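ChIP-seq libraries of the 22Rv1 prostate cancer cell line were compared through the peak lists deposited for them. The series holds 22 samples. Lists of 8 samples were used, 1 library per group: H3K27me3, Pol2S5p and E2F3, each in Ctrl and in cells overexpressing H1-10, and Pol2S5p with a control siRNA or an siRNA against E2F3. The other 14 samples were not analysed here. They are 10 inputs and 4 libraries of H1-10 itself, which per the labels were made with an antibody against Flag from cells overexpressing H1-10, with a control treatment or an inhibitor of H1-10. Groups were taken from the sample labels.

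Per the submitters' processing notes, FastQC, fastp and Bowtie were used and the genome build is hg19; their versions and settings, the peak caller, its threshold and the input library behind each list are not given in the sources used here. Peaks were called by the authors per library and not on pooled libraries, since each list belongs to 1 sample. Each deposited list gives a peak score, a fold enrichment at the summit, which is a ratio to the background of the authors' caller, and -log10 p and -log10 q values of the authors' caller. The deposited summit offset counts base pairs from the peak start. The lowest -log10 q in any list was 1.30. Peak names carry a folder label that is the same for the H3K27me3 lists and the Ctrl and H1-10 OE lists of Pol2S5p, and another for the E2F3, siCtrl and siE2F3 lists; a difference in the authors' processing between these sets cannot be excluded. Each pair compared lies within 1 such label, as do overlaps of E2F3 with siCtrl or siE2F3. Overlaps of E2F3, siCtrl or siE2F3 with H3K27me3 or with the Ctrl and H1-10 OE lists of Pol2S5p cross it.

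Rows that overlapped or touched were joined into regions, which changed no list: the number of regions equalled the number of peaks in all 8. A region counted as shared where it overlapped a region of the other list by at least 1 bp. Shares carry 95% Wilson intervals and differences of shares Newcombe intervals, which cover counting error only. Regions are not replicates, so no p-value was computed. Expected overlaps came from 100 random placements of the regions on their own chromosome, and from 10 in the pairwise table. Peak strength was ranked by -log10 p within a list, in 10 classes of equal size, or in 3 for the loss under siE2F3. Covered length was summed in windows of 500 kb. Regions of at least 10 kb were called long. Coordinates are 1-based on hg19. The read depth of the libraries is unknown here, so list length could not be scaled to depth.

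Regions were named by a rule set before the data were examined: the 5 regions with the highest -log10 q in one list only, for each direction of each comparison, with no region of the other list within 5 kb. The rule chose 40 regions, of which 2 are not reported here. Some regions and windows are likewise not reported, and rankings of windows, and of regions by length or fold, cover those reported here. Regions that the text names from windows or by length were chosen after their values were seen. A gene annotation of hg19 was not used here, so regions are given by position. For the same reason the planned counts of promoters and the 10 gene lists set beforehand were not tested.

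Settings chosen beforehand for comparison were a -log10 q of at least 5, equal numbers of the strongest peaks, 50% reciprocal overlap, the summit inside a region of the other list, peaks within 1 kb merged, an H3K27me3 distance of 1 kb in place of 5 kb, and the E2F3 regions of Ctrl in place of H1-10 OE. Autosomes alone and the siCtrl list in place of the Pol2S5p list of H1-10 OE were added after the data were seen. The overlap code was tested on simulated lists with planted copies of regions: all 5000 copies planted from the Pol2S5p Ctrl list of 35493 regions and all 2000 from the E2F3 Ctrl list of 22988 regions were found. Each copy was moved by only a small part of its width, so correct code had to find it. This checks the code and not the power to detect differences. Of the regions without a copy, 0.548% and 0.00953% were also met. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The 50% reciprocal overlaps and checks of the overlap code used bedtools 2.31.1.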

Results

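Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 3 targets in 22Rv1, an established human prostate cancer cell line. The targets were H3K27me3, a histone mark of Polycomb-silenced chromatin, RNA polymerase II phosphorylated on serine 5 of its C-terminal repeats (Pol2S5p), the form found at initiating genes, and E2F3, a transcription factor of the cell cycle. The factor varied was H1-10, a linker histone variant, which was overexpressed (H1-10 OE) or not (Ctrl). A second pair of Pol2S5p libraries carried a control siRNA (siCtrl) or an siRNA against E2F3 (siE2F3). Of the 22 samples of the series, 8 entered the comparisons, each with 1 list of peaks called on that library alone. No group had a replicate, so no difference below has a replicate check and no p-value is given. Every contrast of H1-10 OE with Ctrl is between single libraries, in which added H1-10 was not separated from other differences in library or cells. Intervals are 95% Wilson intervals, which cover counting error only.

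The lists differed widely in length. H3K27me3 had 2540 regions in Ctrl and 18395 in H1-10 OE, covering 1.52 and 10.1 Mb. Pol2S5p had 35493 regions in Ctrl and 40626 in H1-10 OE, covering 43.1 and 39.1 Mb. E2F3 had 22988 regions in Ctrl and 4296 in H1-10 OE, covering 15.6 and 1.95 Mb. The siCtrl and siE2F3 Pol2S5p lists were the longest, with 83650 and 83067 regions over 103 and 90.7 Mb. Read depth per library is unknown here, so the number of regions in a list reflects the library and its threshold as well as the chromatin. Fold enrichments and significance values of peaks are the authors' and serve to describe, rank or filter the peaks of their own list; their levels are not compared between lists.

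**Figure D1:**
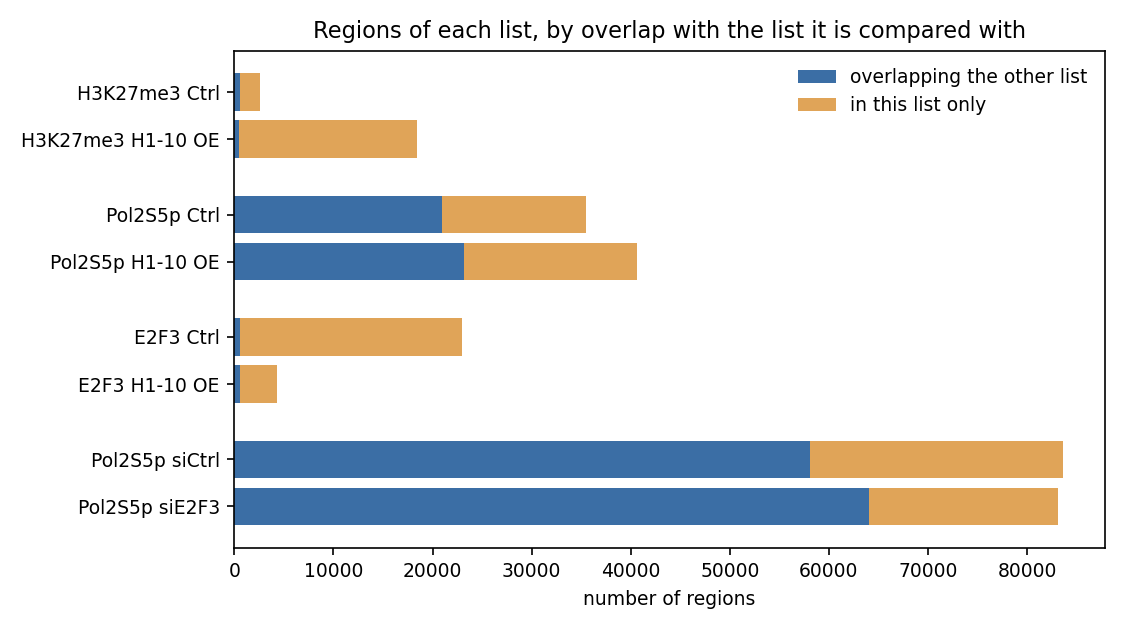
Number of regions (x axis) in each of the 8 peak lists, split into those that overlap the list it is compared with by at least 1 bp and those found in that list only; 1 library per list. Shared regions form the larger part of all 4 Pol2S5p lists and a small part of both E2F3 lists, where 605 of 4296 H1-10 OE regions overlapped the Ctrl list.

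The comparison of H3K27me3 between H1-10 OE and Ctrl asks where this silencing mark was found with and without added H1-10. The H1-10 OE list held 7.24 times as many regions, most of them at other places than the Ctrl regions. The regions were short, with a median width of 460.5 bp in Ctrl and 433 bp in H1-10 OE. A -log10 q of at least 5 was reached by 26.8% of the Ctrl and 19.0% of the H1-10 OE regions. A place outside the regions of a list may therefore still carry the mark. Of the Ctrl regions, 569 (22.4%, interval 20.8 to 24.1%) overlapped an H1-10 OE region, and 1971 were found in Ctrl only. Of the H1-10 OE regions, 517 (2.81%, 2.58 to 3.06%) overlapped a Ctrl region, and 17878 were found in H1-10 OE only. Random placement of the Ctrl regions on their chromosomes gave a mean overlap of 0.929%.

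Blocks near the ends of chromosomes changed in both directions. On chromosome 7, the 500-kb window from 1 to 1.5 Mb held 87.1 kb of H3K27me3 regions in Ctrl and 1.29 kb in H1-10 OE, while the window from 155.5 to 156 Mb held 10.0 kb in Ctrl and 149 kb in H1-10 OE. The window from 157.5 to 158 Mb of the same chromosome held 5.26 kb in Ctrl, a further 128 kb being added in H1-10 OE, and that from 142.5 to 143 Mb of chromosome 8 went from 0.304 to 123 kb. On chromosome 10 the window from 134.5 to 135 Mb went from 53.9 to 11.1 kb. Chromosome 7 held 18.7% of the Ctrl regions (17.2 to 20.3%) and 10.7% of the H1-10 OE regions (10.3 to 11.2%). Chromosome X held 0 of the 2540 Ctrl regions and 1319 of the 18395 H1-10 OE regions (7.17%, 6.81 to 7.55%); a difference in cells other than added H1-10 was not excluded for these H3K27me3 values.

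Among the most significant regions found in Ctrl only were a pair on chromosome 7 at 1279058 to 1284647 and 1284999 to 1288749, with fold enrichments of 11.1 and 12.8. The region with the highest significance in Ctrl only, on chromosome 2 at 162138049 to 162138494, had a fold of 4.33, below the median of 4.83 of its list. No filter for places of high background was applied here, so this region is not read as a change of the mark. In H1-10 OE only, the leading region lay on chromosome 8 at 86556000 to 86557049 with a fold of 19.0, followed by chromosome 15 at 102293639 to 102294109 with a fold of 13.5. The H1-10 OE region on chromosome 1 at 70033037 to 70035689, with a fold of 10.6, overlapped both a Pol2S5p and an E2F3 region of the Ctrl lists and none of the H1-10 OE lists of those targets. Among the strongest 10% of each list, 36.6% of the Ctrl regions (30.9 to 42.7%) and 12.7% of the H1-10 OE regions (11.2 to 14.3%) were shared. With -log10 q of at least 5 in both lists, 538 regions remained in Ctrl only and 3368 in H1-10 OE only. With equal numbers of the strongest peaks, 2540 per list, 2214 were in Ctrl only and 2278 in H1-10 OE only.

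The comparison of Pol2S5p between H1-10 OE and Ctrl asks where initiating polymerase was found with and without added H1-10. Most strong regions were shared, and regions found in one list only were weaker at the median, with some strong exceptions in each list. Of the Ctrl regions, 20949 (59.0%, 58.5 to 59.5%) overlapped an H1-10 OE region, and 14544 did not. Of the H1-10 OE regions, 23221 (57.2%, 56.7 to 57.6%) overlapped a Ctrl region, and 17405 did not. The median fold enrichment was 8.84 at shared regions and 4.08 at regions found in one list only in Ctrl, and 8.20 and 4.61 in H1-10 OE. In the weakest 10% of the Ctrl regions 25.6% were shared, and in the strongest 10% the share was 98.2% (97.7 to 98.6%).

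Regions of at least 10 kb numbered 245 in Ctrl and 41 in H1-10 OE among those reported here. The siCtrl and siE2F3 lists, whose peak names carry H1-10 overexpression, held 849 and 612 such regions. A median of 68.3% of the length of those in Ctrl was covered by H1-10 OE regions; 52 of the 245 were covered over less than 10%, and 31 had no overlap. The 5 windows with the largest loss, picked as extremes, were as follows. The window from 102 to 102.5 Mb of chromosome 4 held 242 kb of Pol2S5p regions in Ctrl and 3.26 kb in H1-10 OE, and siCtrl and siE2F3 held 3.61 and 3.35 kb there. The window from 66.5 to 67 Mb of chromosome X went from 187 to 0.378 kb, that from 106.5 to 107 Mb of chromosome 11 from 166 to 1.05 kb, that from 85 to 85.5 Mb of chromosome 15 from 150.5 to 21.8 kb with 64.3 kb in siCtrl, and that from 100.5 to 101 Mb of chromosome 2 from 129 to 3.54 kb. The longest Ctrl region, on chromosome X at 53251580 to 53350658, spanned 99.1 kb; 3.15 kb of it was covered in H1-10 OE. Another Ctrl region of 57.4 kb at 66762604 to 66819997 of chromosome X was covered over 0.378 kb in H1-10 OE. The windows and long regions were chosen after their values were seen.

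Among the windows reported here, the 5 with the largest gain in H1-10 OE changed by fewer kilobases, and 4 of them lay on chromosome X. The window from 112 to 112.5 Mb went from 1.55 kb in Ctrl to 51.8 kb in H1-10 OE, with 56.1 kb in siCtrl and 55.1 kb in siE2F3. The window from 45.5 to 46 Mb went from 0 to 28.8 kb, with 30.2 kb in siCtrl and 28.9 kb in siE2F3. The fifth, from 30.5 to 31 Mb of chromosome 16, went from 97.3 to 124 kb.

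**Figure D2:**
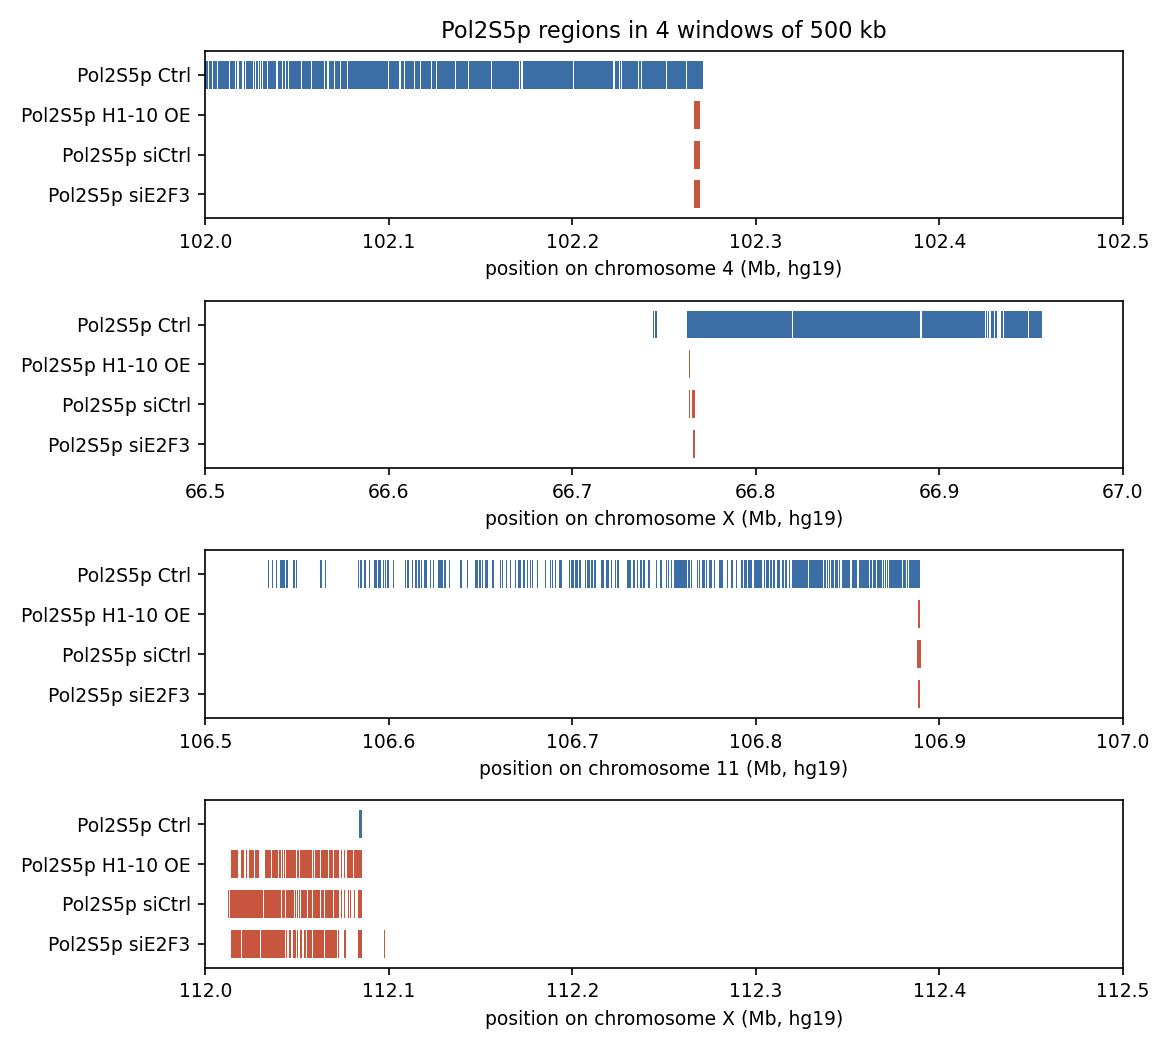
Pol2S5p regions (bars, drawn to scale) of the 4 lists in 4 windows of 500 kb, with position in Mb on the x axis and 1 row per list. In the windows of chromosomes 4 and 11 and in that from 66.5 Mb of chromosome X the Ctrl list covers 242, 166 and 187 kb; in the window from 112 Mb of chromosome X the other 3 lists cover between 51.8 and 56.1 kb and Ctrl 1.55 kb.

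The most significant Pol2S5p region found in Ctrl only lay on chromosome 1 at 147993657 to 147994893, with a fold of 44.4. The third lay on chromosome 6 at 26042522 to 26046829 with a fold of 39.3, and the fifth on chromosome 9 at 6715684 to 6717719 with a fold of 37.3. These 3 overlapped an E2F3 region of Ctrl and no region of any of the other Pol2S5p lists. The second, on chromosome 1 at 144533324 to 144534765 with a fold of 27.3, was also found in E2F3 of Ctrl and in siCtrl, and the fourth, on chromosome 17 at 25415498 to 25417310 with a fold of 31.5, in none of the other lists. Places of high background were not filtered from the Pol2S5p lists either, so such places among these Ctrl only regions were not excluded. In H1-10 OE only, the leading region lay on chromosome 11 at 5245957 to 5247489. Its fold of 220 was the highest reported here for this list, and none of the other 7 lists had a region there; the source of this signal was not tested, so it is not read here as polymerase. A region on chromosome 13 at 77458402 to 77461299, with a fold of 34.2, was also present in siCtrl and siE2F3. Requiring 50% reciprocal overlap raised the counts found in one list only to 22040 and 27173, and a -log10 q of at least 5 lowered them to 6801 and 7901. Merging peaks within 1 kb lowered the Ctrl count to 8498.

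The comparison of E2F3 between H1-10 OE and Ctrl asks where this factor was found with and without added H1-10. The H1-10 OE list held 0.187 times as many regions, and most of them were not Ctrl regions. Of the Ctrl regions, 595 (2.59%, 2.39 to 2.80%) overlapped an H1-10 OE region, and 22393 were found in Ctrl only. Of the H1-10 OE regions, 605 (14.1%, 13.1 to 15.2%) overlapped a Ctrl region, and 3691 did not. In Ctrl, shared regions had a median fold of 37.5 against 8.85 for regions found in Ctrl only, while in H1-10 OE shared regions had the lower median fold, 5.07 against 6.33. Ranked by -log10 p the H1-10 OE list ran the other way, with 2.56% (1.43 to 4.52%) shared in its weakest 10% and the highest share in its strongest 10%. Of the strongest 10% of the Ctrl regions, 16.9% (15.4 to 18.5%) were found in H1-10 OE, and of the strongest 10% of the H1-10 OE regions, 30.2% (26.1 to 34.7%) were found in Ctrl. With equal numbers of the strongest peaks, 4296 per list, 3878 regions were found in Ctrl only and 3866 in H1-10 OE only.

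The spread of the regions over chromosomes differed between the lists. Chromosome 13 held 2.12% of the Ctrl regions (1.94 to 2.32%) and 12.8% of the H1-10 OE regions (11.8 to 13.8%), and chromosome 19 held 7.28% (6.95 to 7.62%) and 0.745% (0.528 to 1.05%). The window from 67.5 to 68 Mb of chromosome 13 went from 0.645 kb in Ctrl to 32.3 kb in H1-10 OE, and that from 72 to 72.5 Mb from 2.66 to 23.9 kb. The window from 1 to 1.5 Mb of chromosome 19 went from 52.9 kb to 0, and that from 145.5 to 146 Mb of chromosome 8 from 43.7 kb to 0. In both of these windows Pol2S5p regions covered 168 and 123 kb in Ctrl and 132 and 98.0 kb in H1-10 OE.

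The 5 most significant E2F3 regions found in Ctrl only all overlapped a region in each of the 4 Pol2S5p lists. They included chromosome 1 at 160067856 to 160069201 with a fold of 77.2, chromosome 3 at 196729446 to 196730853 with a fold of 79.7, and chromosome 19 at 4908805 to 4910407 with a fold of 87.4. The 5 most significant in H1-10 OE only each overlapped a Pol2S5p region of H1-10 OE and none of Ctrl, while 4 of them also overlapped siCtrl and 2 overlapped siE2F3. They included chromosome 7 at 80505694 to 80507077 with a fold of 77.8, chromosome 8 at 37159659 to 37160847 with a fold of 65.2, and chromosome 2 at 210360363 to 210361575 with a fold of 58.9.

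**Figure D3:**
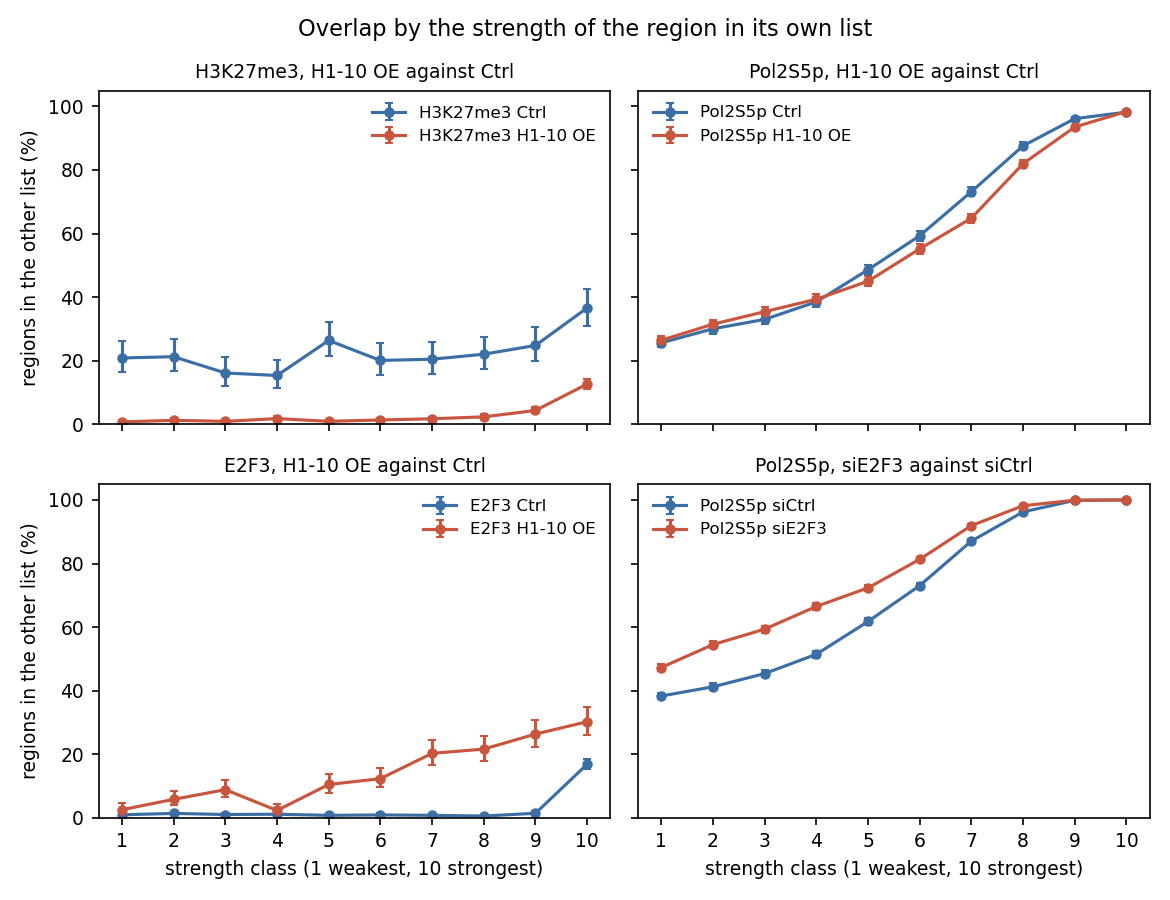
Share of regions that overlap the other list of each comparison (y axis, %) by strength class of the region in its own list (x axis, 10 classes of equal size by -log10 p, 10 the strongest); bars are 95% Wilson intervals. In the Pol2S5p comparison of H1-10 OE with Ctrl the share in the strongest class is 98.2% of Ctrl and 98.4% of H1-10 OE regions, and in the E2F3 comparison 16.9% and 30.2%.

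Setting E2F3 against Pol2S5p shows whether the E2F3 regions that differed lay at initiating polymerase. E2F3 regions found in Ctrl only lay at Pol2S5p regions in both conditions: 67.7% (67.0 to 68.3%) overlapped the Pol2S5p list of Ctrl and 64.2% (63.5 to 64.8%) that of H1-10 OE. Of the 595 Ctrl regions shared with H1-10 OE, 80.5% (77.1 to 83.5%) and 82.4% (79.1 to 85.2%) did so. E2F3 regions found in H1-10 OE only differed: 74 of 3691 (interval 1.60 to 2.51%) overlapped Pol2S5p of Ctrl, where 100 random placements reached up to 2.09%. Of the same regions, 21.7% (20.4 to 23.0%) overlapped Pol2S5p of H1-10 OE, where random placements reached up to 2.11%. With the siCtrl list in place of the Pol2S5p list of H1-10 OE, an alternative added after the data were seen, this share was 8.10%. With -log10 q of at least 5 in all lists, the share in Pol2S5p of Ctrl was 1.16%.

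Setting Pol2S5p against H3K27me3 shows how the silencing mark and initiating polymerase were placed. Pol2S5p regions found in H1-10 OE only lay within 5 kb of H3K27me3 of Ctrl more often than other Pol2S5p regions did: 2.79% (2.55 to 3.04%), against 0.323% (0.243 to 0.429%) of those in Ctrl only and 0.487% (0.401 to 0.591%) of shared ones. Random placement of the first set gave a mean of 0.698% and at most 0.879%. H3K27me3 of H1-10 OE lay near 2.85% (2.59 to 3.13%) of the Pol2S5p regions found in Ctrl only, 1.60% (1.43 to 1.80%) of those in H1-10 OE only and 1.29% (1.14 to 1.45%) of shared ones. These shares lay below their random means of 4.66, 4.72 and 5.04%. A distance of 1 kb gave 1.90% for H1-10 OE only regions near H3K27me3 of Ctrl and 0.131% for Ctrl only regions. With the siCtrl list in place of H1-10 OE and the distance kept at 5 kb, 1.29% of siCtrl only regions lay near H3K27me3 of Ctrl.

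The comparison of siE2F3 with siCtrl asks how Pol2S5p changed when E2F3 was targeted. The peak names of both lists carry a label of H1-10 overexpression that the sample labels do not give. The lists were close in length and in place. Of the siCtrl regions, 58083 (69.4%, 69.1 to 69.7%) overlapped an siE2F3 region, and 25567 did not. Of the siE2F3 regions, 64070 (77.1%, 76.8 to 77.4%) overlapped a siCtrl region, and 18997 did not. Every one of the 8365 regions in the strongest 10% of siCtrl was also found in siE2F3, and of the weakest 10%, 38.3% (37.3 to 39.4%) were. Total covered length was 103 Mb in siCtrl and 90.7 Mb in siE2F3.

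The windows that lost most Pol2S5p under siE2F3 held at least 55.9 kb of it in each of the 4 Pol2S5p lists. The window from 0.5 to 1 Mb of chromosome 19 went from 227 to 179 kb, that from 11 to 11.5 Mb of the same chromosome from 190 to 144 kb, and that from 38 to 38.5 Mb of chromosome 22 from 261 to 215 kb. The 3 windows that gained most all lay on chromosome 19, led by that from 37 to 37.5 Mb, which went from 44.3 to 63.5 kb, and that from 52.5 to 53 Mb, which went from 45.2 to 58.2 kb. The most significant regions found in siCtrl only were on chromosome 11 at 66189052 to 66189493, with a fold of 13.7, and on chromosome 2 at 178462285 to 178462956, with a fold of 12.2. In siE2F3 only, the leading region lay on chromosome 1 at 50489591 to 50489917 with a fold of 8.54. With -log10 q of at least 5 in both lists, 12981 regions were found in siCtrl only and 9806 in siE2F3 only. With 50% reciprocal overlap, 44884 and 44301 were, and with peaks within 1 kb merged, 13760 and 11188.

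The loss of Pol2S5p regions under siE2F3 was set against E2F3 occupancy within 3 classes of region strength of equal size. Regions with an E2F3 region of the H1-10 OE list were lost more often than those without. Background in this list and reads passed between libraries stay open below, so its regions may not all mark E2F3 binding. In the middle class 89 of 129 regions with E2F3 (69.0%, 60.6 to 76.3%) were absent from siE2F3, against 31.7% (31.1 to 32.2%) of 27754 without, a difference of 37.3 percentage points (28.9 to 44.7). The difference was 14.7 points (2.09 to 24.6) in the weakest class, with 58 regions with E2F3, and 3.04 points in the strongest, where 5.11% (3.58 to 7.25%) of 567 regions with E2F3 were lost against 2.08% (1.92 to 2.26%) without. With E2F3 regions of Ctrl the difference was 4.82 points in the weakest class, from 62.4% (58.1 to 66.6%) with and 57.6% (57.0 to 58.2%) without. It was 1.44 (-1.60 to 4.61) in the middle class, and of the opposite sign, -2.63 (-2.97 to -2.31), in the strongest. The regions with E2F3 of Ctrl numbered 498, 912 and 13025 from the weakest to the strongest class. With siCtrl peaks of -log10 q of at least 5 only, the differences with E2F3 of H1-10 OE were 49.6, 22.4 and 0.820 points from the weakest to the strongest class. The opposite direction, siE2F3 regions absent from siCtrl, was not part of the plan. There the differences with E2F3 of Ctrl were -29.1, -16.3 and -1.92 points, in the same order of classes. With E2F3 of H1-10 OE they were -8.86 (-21.4 to 5.93), -12.5 and -1.13 points.

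Pairwise overlaps of the 4 Pol2S5p lists give a scale for how far lists of 1 antibody differed between libraries. No 2 of these libraries are replicates by the labels. Of the H1-10 OE regions, 88.6% (88.3 to 88.9%) overlapped siCtrl and 85.1% (84.8 to 85.4%) overlapped siE2F3, against 57.2% for Ctrl. Of the Ctrl regions, 77.5% (77.1 to 78.0%) overlapped siCtrl, 74.6% (74.1 to 75.0%) siE2F3 and 59.0% H1-10 OE. Of the siCtrl regions, 27.5% overlapped Ctrl and 31.8% H1-10 OE, and with equal numbers of the strongest peaks these shares were 52.4 and 57.1%. For siE2F3 the shares were 28.4% and 32.6%, and with equal numbers of peaks 52.8 and 56.8%. Across 5500 windows of 500 kb, which are not independent replicates, Spearman's rho of covered length was 0.992 between siCtrl and siE2F3, 0.963 between H1-10 OE and siCtrl, and 0.880 between Ctrl and H1-10 OE. Of the Ctrl regions, 20076 (56.6%) were found in all of the other 3 lists and 6923 (19.5%) in none of them, and 11736 H1-10 OE regions (28.9%) were found in siCtrl and siE2F3 and not in Ctrl.

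**Figure D4:**
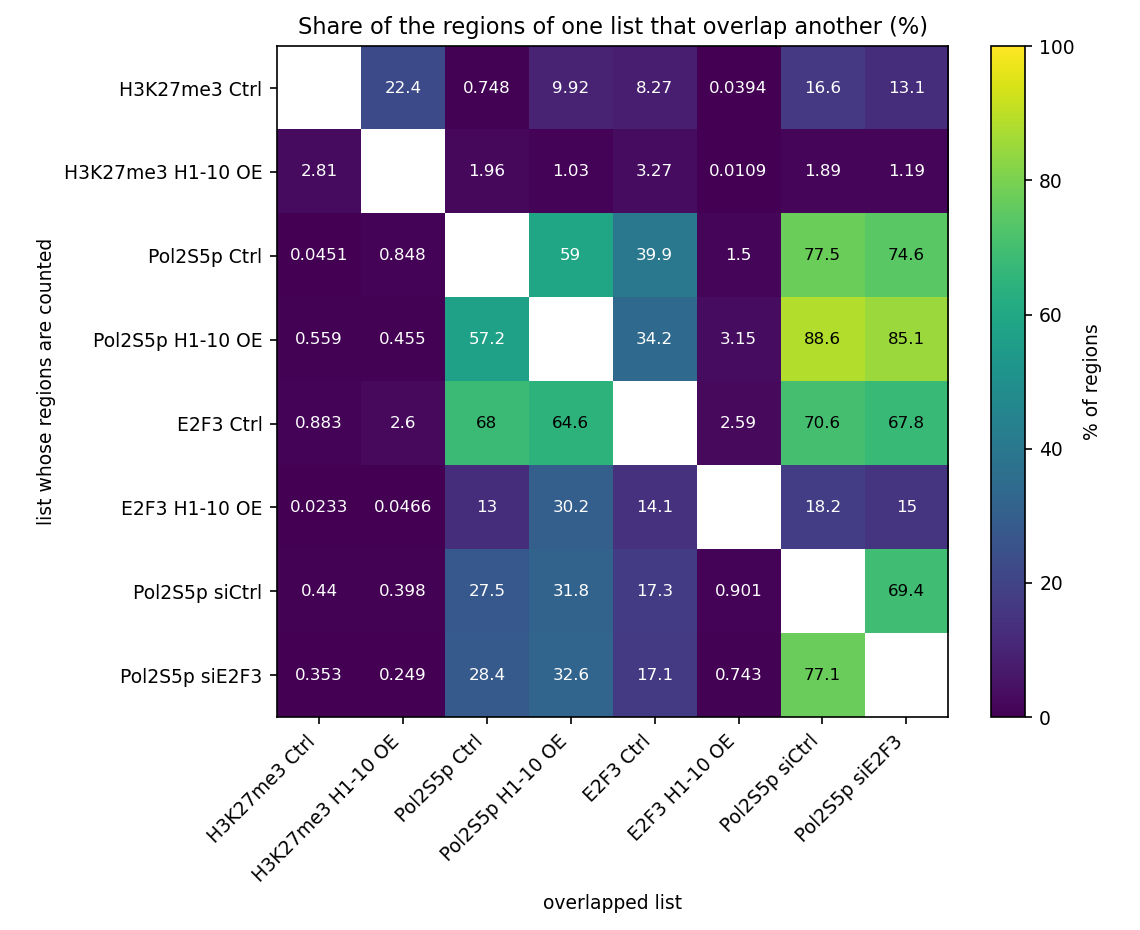
Share (%) of the regions of the list on the y axis that overlap the list on the x axis by at least 1 bp, for the 8 lists; 1 library per list. Of the Pol2S5p H1-10 OE regions 88.6% overlap siCtrl and 57.2% Ctrl, and of the E2F3 Ctrl regions 2.59% overlap E2F3 H1-10 OE.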

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

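Counts of regions in one list only, E2F3 at Pol2S5p, Pol2S5p near H3K27me3, the loss under siE2F3 and overlaps of the Pol2S5p lists were recomputed with 1 choice changed at a time, while shares by chromosome or strength, window lengths and long regions were not; autosomes alone and the siCtrl list in place of the Pol2S5p list of H1-10 OE were chosen after the data were seen. With autosomes alone, and with the summit required inside a region of the other list, all 8 counts of regions found in one list only stayed within 1.5 times. No paired analysis was possible because each group holds 1 library, and leaving out a library was not possible for the same reason. The promoter and gene-list alternatives were not run. Fewer regions were compared under a stricter threshold and under merging, which by itself lowers counts. Reciprocal overlap raises counts by its construction. The share in one list only could change as well. With -log10 q of at least 5, 6801 of 21861 Pol2S5p Ctrl regions were in Ctrl only, against 14544 of 35493 without it. For H3K27me3 of Ctrl these counts were 538 of 680, against 1971 of 2540. For the other values the cause was not tested. Unknown read depth limits how far list lengths can be read.

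With -log10 q of at least 5 in both lists, regions found in one list only numbered 538 and 3368 for H3K27me3 in Ctrl and H1-10 OE, 6801 and 7901 for Pol2S5p, 1985 for E2F3 in H1-10 OE, and 12981 and 9806 for siCtrl and siE2F3. With equal numbers of the strongest peaks, H3K27me3 in H1-10 OE gave 2278 of 2540 and E2F3 in Ctrl 3878 of 4296. With 50% reciprocal overlap, Pol2S5p gave 22040 in Ctrl and 27173 in H1-10 OE, and siCtrl and siE2F3 gave 44884 and 44301. With peaks within 1 kb merged, Pol2S5p Ctrl gave 8498, siCtrl 13760 and siE2F3 11188. With siCtrl in place of H1-10 OE, Pol2S5p gave 7974 in Ctrl only and 60608 in siCtrl only.

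For E2F3 regions at Pol2S5p with -log10 q of at least 5 in all lists, Ctrl only regions gave 69.3% in Ctrl and 65.4% in H1-10 OE, shared regions 84.3 and 86.6%, and H1-10 OE only regions 1.16 and 24.2%. With the E2F3 summit inside a Pol2S5p region, Ctrl only regions gave 65.7 and 61.5%, and H1-10 OE only regions 20.0% in H1-10 OE. With siCtrl in place of H1-10 OE, Ctrl only regions gave 70.4% and H1-10 OE only regions 8.10%.

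For Pol2S5p near H3K27me3 of Ctrl and of H1-10 OE, a distance of 1 kb gave 0.131 and 1.97% of Ctrl only regions, 1.90 and 1.04% of H1-10 OE only regions, and 0.215 and 0.706% of shared regions. With -log10 q of at least 5 in all lists, Ctrl only regions near H3K27me3 of Ctrl gave 0.221%, H1-10 OE only regions 1.92 and 1.03%, and shared regions 0.193 and 0.664%. With siCtrl in place of H1-10 OE, Ctrl only regions near H3K27me3 of H1-10 OE gave 4.01%, and siCtrl only regions 1.29 and 0.865%.

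For Pol2S5p lost under siE2F3 at E2F3 regions, siCtrl peaks with -log10 q of at least 5 gave differences of 49.6, 22.4 and 0.820 percentage points from the weakest to the strongest class. With E2F3 regions of Ctrl the middle class gave 1.44 points and the strongest reversed to -2.63 points; the cause was not tested.

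With equal numbers of the strongest peaks, 56.5% of Pol2S5p Ctrl regions lay in H1-10 OE, 68.1% in siCtrl and 64.7% in siE2F3. Of H1-10 OE regions 61.3% lay in Ctrl, 81.3% in siCtrl and 76.7% in siE2F3. Of siCtrl regions 52.4% lay in Ctrl and 57.1% in H1-10 OE, and of siE2F3 regions 52.8 and 56.8%.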

Other observations

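All tests in this part were chosen after the result was seen, except the correlation of fold enrichment between E2F3 and Pol2S5p in H1-10 OE, whose limits were set before it was computed.

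E2F3 regions of Ctrl followed Pol2S5p by strength. In the weakest of 5 classes of equal size, 41.5% (40.0 to 42.9%) overlapped Pol2S5p of Ctrl, and in the strongest 95.3% (94.7 to 95.9%) did. H3K27me3 regions of Ctrl overlapped Pol2S5p of H1-10 OE in 9.92% (8.82 to 11.1%) and Pol2S5p of Ctrl in 0.748% (0.479 to 1.17%), with random means of 2.65 and 2.72%. The same regions overlapped siCtrl in 16.6% (15.2 to 18.1%) and siE2F3 in 13.1% (11.9 to 14.5%), with random means of 5.81 and 5.37%, so Pol2S5p of Ctrl stood apart from all 3 other lists. Of the H3K27me3 regions of H1-10 OE, 1.03% (0.897 to 1.19%) overlapped Pol2S5p of H1-10 OE and 1.96% (1.77 to 2.17%) Pol2S5p of Ctrl, and 1.89 and 1.19% overlapped siCtrl and siE2F3. The 10 fullest windows of 500 kb held 26.8% of the covered length of H3K27me3 in Ctrl and 10.2% in H1-10 OE.

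A set of strong autosomal Pol2S5p regions parted the Ctrl list from the other 3 lists: 1.33% (0.999 to 1.77%) of the 3458 strongest Ctrl regions were in none of the others, and 55 of the 3930 strongest H1-10 OE regions were in siCtrl and siE2F3 and not in Ctrl. Lower sensitivity of the other libraries stays open for the first set: 2.32% (1.18 to 4.51%) of the strongest 1% of the Ctrl regions and 1.22% (0.891 to 1.67%) of the next 9% were in none of the others, an order opposite to what it would give but with overlapping intervals, and siCtrl and siE2F3 were the longer lists, with 83650 and 83067 regions against 35493 in Ctrl. A wrong label on the Pol2S5p Ctrl library alone was tested first on H3K27me3. There 0 of 46 Ctrl only regions lay near H3K27me3 of Ctrl and 3 near that of H1-10 OE, with overlapping intervals. Of the 55 regions 12 (21.8%, 12.9 to 34.4%) lay near that of Ctrl and 2 (3.64%, up to 12.3%) near that of H1-10 OE, which runs as the labels say. In a second test the E2F3 list of Ctrl held 82.6% (69.3 to 90.9%) of these 46 regions and 49.1% (36.4 to 61.9%) of the 55. Such an error alone would give the 46 no higher share. The sets were not matched on strength, so this argues against the error without excluding it. An effect of H1-10 and a difference in cells between the Ctrl libraries and the rest cannot be told apart, since 5.00% of the strongest siCtrl regions were also absent from Ctrl and the peak names of siCtrl and siE2F3, though not their sample labels, carry H1-10 overexpression. Each may account for part of the pattern.

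The E2F3 list of H1-10 OE was short and placed unlike that of Ctrl; lower depth alone would leave its strongest regions inside the Ctrl list, and 30.2% of the strongest 10% were. Background scattered evenly along the chromosomes would leave the strongest of 5 equal classes of the regions found in H1-10 OE only at the level of random placements. Of these 738 regions, 21.0% (18.2 to 24.1%) met siCtrl, where placements reached 6.50%. In siE2F3 10.0% (8.06 to 12.4%) were met, where placements reached 5.56%. Pol2S5p of Ctrl met 0.949% (placements up to 3.25%). An earlier form of the test, which also asked for an excess there, left the whole set open and would leave this class open. The placements were even along each chromosome, so background that gathers at particular places was not excluded. For the other 2953 regions evenly scattered background stays open, with 4.88% (4.16 to 5.71%) in siCtrl, 3.45% in siE2F3 and 2.27% (1.79 to 2.87%) in Ctrl, where placements reached 4.57, 3.86 and 1.86%. Pol2S5p of H1-10 OE was not used in this test, since reads passed between it and the E2F3 library could also give an overlap. Of the E2F3 regions outside both Ctrl lists, it met 5.80% (4.32 to 7.75%) in the weakest of 5 classes and 53.5% in the strongest. Weaker enrichment of the same sites with no added background would keep the chromosome shares, and chromosome 13 held 12.8% of the H1-10 OE regions against 2.12% in Ctrl. The share was taken over the whole list, part of which stays open as background. It therefore cannot exclude weaker enrichment joined by background regions. That cause, a change of E2F3 binding with H1-10 and a difference in antibody performance, library or cells may remain, untested with 1 library per group.

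E2F3 regions of H1-10 OE that lay outside both Ctrl lists coincided with Pol2S5p of H1-10 OE at 751 of 3617 places. If this were a property of H1-10 OE cells that any Pol2S5p library of them shows, the longer siCtrl list would hold at least as many, and it held 251, with the caveat that its H1-10 overexpression is known from peak names only. Reads passed between the E2F3 and Pol2S5p libraries of H1-10 OE may be a candidate source, since 532 of these regions were in both and in neither siCtrl nor siE2F3. Spearman's rho of fold enrichment across these 532 regions, which are not independent replicates, was 0.240 (bootstrap interval 0.156 to 0.326), above the highest of 2000 shuffles (0.164) and above the -0.152 at 460 regions also in both Ctrl lists, but between the limits set beforehand, so the test left this open.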
